A study of Craterostigma plantagineum with 12 samples.

How the data were processed

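Leaves of vegetatively propagated Craterostigma plantagineum plants were sampled in 4 states, with 3 libraries each: fresh at 100% relative water content (RWC), at about 60% RWC after drying in pots, at 2% RWC, and after 24 h of submersion in water. Per the labels' protocols, plants grew at 60% relative humidity with 14 h of light and 8 h of dark, and each library came from its own pool of leaves. Per the labels, stranded libraries of total RNA were sequenced as paired ends in 5 MiSeq runs and counted on a transcriptome assembly of the species. The pool for that assembly also held root and flower samples. The assembler, the mapper with its settings, the strand setting and whether a read pair counts as 1 or 2 are not given in the sources used here. The samples after 48 h of rehydration that the protocol names were not used here. The 3 columns for rehydrated leaves were matched to the 24 h samples by their names.

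The counts are whole-number total gene reads per contig, deposited by the authors, including reads that match several contigs. A second set of counts, per the file headers, holds reads unique to a contig. Unique reads made up 98.52 to 98.71% of the total in each library. The RPKM values were made by the authors from the total reads, the contig length and the library total, and recomputing them from the deposited counts gave the same values within 1.6e-08. The p-value and FDR columns hold the authors' test across the 4 states on what the file headers call original values, and neither those values nor the software are explained there. The description of each contig is a text of the deposited annotation, and for some contigs it names another protein than the best-hit column does. Of 48045 contigs, 40906 had a description from green plants. Contig lengths had a median of 522 bases, from 223 to 11931.

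Tests were run in R 4.3.3 on the total gene reads of all 12 libraries in a single edgeR 4.0.16 fit with a mean per state, TMM scaling (factors 0.863 to 1.186), filterByExpr by state (minimum count 10, minimum total 15) and robust quasi-likelihood dispersions. The filter left 46494 contigs, and 12 of the 1551 left out had no read in any library. The 5 comparisons were 60% against 100% RWC, 2% against 100%, 2% against 60%, rehydrated against 2% and rehydrated against fresh, with an F test across the 4 states beside them. A contig was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided and without a fold threshold. The SE of a log2 fold is its absolute value divided by the square root of its F statistic. For each comparison 50 gene lists, 15 of them core lists and 7 of them markers, were tested with camera of limma 3.58.1. Camera used a preset correlation of 0.01 and, beside it, an estimated correlation, whose adjusted p is printed, and fry was run as an alternative. Lists were made by words in the contig descriptions, some share contigs, and their p was adjusted over the 50 lists of a comparison. The tests, lists, thresholds and most alternatives were fixed before the data were examined.

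Named contigs followed a rule. In the comparisons of 60% and 2% RWC with fresh leaves and of rehydrated leaves with 2% RWC, it took 5 contigs with the highest and 5 with the lowest log2 fold among called, described contigs in the upper 50% of tested contigs by mean level. They had no overlap between the replicates of both states, as 10% of contigs would by chance, and only the first contig of a description was taken. It also took the member of each core list with the highest mean level and the called member with the largest fold, and 5 contigs at the highest level whose description or best hit names the species. For 2% against 60% RWC and rehydrated against fresh leaves it took 3 and 3 by fold. The text leaves out some list members, and values of these contigs in other comparisons were added to follow them through the cycle. Where a state had no read, a fold is a bound with 3 counts per library as the floor, which is 0.141 to 0.203 CPM, and with 1 to 3 reads the ratio is given with its 95% counting interval. RPKM values are deposited ones, given as mean ± SD.

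The procedure was tested on simulated counts. For 2% against 100% RWC, with 46011 contigs, 3 of 67 contigs changed 2-fold were called (4.5%), 42 of 67 changed 4-fold (62.7%) and 54 of 66 changed 8-fold (81.8%), with 5 of 45811 unchanged contigs. Only 200 contigs were changed, so the adjusted p was stricter than in the real comparison, and these shares need not hold there. Camera called a simulated list of changed contigs and did not call a list of unchanged ones. Contigs were drawn independently of each other there, while the median estimated correlation within lists was 0.095 in the real comparison. That check therefore does not tell how camera with the preset correlation acts on correlated contigs. In 20 simulations without effect, edgeR called on average 56.6, 55.2, 0, 0 and 87.7 of 46014 contigs in the 5 comparisons, in the order above. Library pairs within a state were checked for duplicates by chi-square per degree of freedom, which was 5.2 to 92.2. The replicate numbers were checked for pairing: after removal of state means, 3 of 18 same-numbered pairs of libraries correlated above 0.1 (r -0.151 to 0.253, other pairs -0.235 to 0.236). The numbers were not treated as pairs.

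The alternatives were DESeq2's size factors in edgeR, no low-count filter, a stricter filter of 50 counts in 3 libraries, the replicate number as a block, a fit of the 6 libraries of a comparison, sums over contigs with the same best hit, the Wald test of DESeq2 1.42.0, an adjusted p below 0.01, a fold of at least 2, and each library left out in turn. Added after the data were seen were unique reads, counts divided by 2, limma's voom with a weight per group, and a fit without the fresh libraries. No genome was used, so no coordinates are given.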

Results

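Craterostigma plantagineum is a resurrection plant whose leaves survive the loss of nearly all their water and become green and active again when watered. Leaf RNA was sequenced in 4 states of this cycle: fresh leaves at 100% relative water content (RWC), leaves at 60% RWC after partial drying, leaves at 2% RWC after full desiccation, and leaves of desiccated plants kept under water for 24 h. Each state had 3 libraries, each made from a separate pool of leaves of 6 to 9 plants. Days of drying differed between the states, and no watered plants of matching time are among the libraries. Water content and time without water therefore cannot be told apart. The expression table held whole-number reads and RPKM (reads scaled to contig length and library total) for 48045 contigs of an assembled transcriptome, and levels are given as RPKM, mean ± SD over the 3 libraries of a state. A contig is an assembled piece of transcript, so several contigs can belong to a single gene, and counts of contigs are not counts of genes. The total reads of replicates 1, 2 and 3 were 17362965, 16880893 and 14784251 for fresh leaves and 17864253, 15295754 and 16533519 for 60% RWC. They were 18160496, 21271288 and 14787562 for 2% RWC and 17114221, 15562432 and 17265650 for rehydrated leaves. The table gives no molecular identifiers. Floors and intervals of read counts cover counting error only, since reads copied by PCR are not independent molecules. The comparisons ask what changes in partial drying (60% against 100% RWC), in full desiccation (2% against 100%), in the later part of drying (2% against 60%) and on rewatering (rehydrated against 2%), and what still differs afterwards (rehydrated against fresh). Contigs are named as in the deposited table, no genome was used, and no genomic coordinates are given.

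The 3 libraries of a state lay close together after drying and farther apart in fresh leaves. Pearson's r of log2 CPM (counts scaled to the library total) across contigs, which are not independent replicates, was 0.967 to 0.973 among the 60% RWC libraries, 0.973 to 0.98 at 2% RWC and 0.943 to 0.971 after rehydration, against 0.832 to 0.866 among the fresh libraries. Fresh and rehydrated libraries correlated at 0.81 to 0.881 with each other, and fresh libraries with 60% and 2% RWC libraries at 0.643 to 0.734 and 0.57 to 0.634. The common biological coefficient of variation was 0.539 in fresh leaves, 0.144 at 60% RWC, 0.14 at 2% RWC and 0.264 after rehydration. In fresh leaves 2787 contigs spanned more than 8-fold between their 3 libraries, against 147, 80 and 251 contigs in the 60% RWC, 2% RWC and rehydrated libraries. Lists that differed widely among the fresh libraries included light-harvesting proteins (2.06, 3.03 and 0.898% of reads in replicates 1, 2 and 3) and lipoxygenases and jasmonate synthesis (0.627, 0.227 and 0.133%). No pair of libraries of the same state matched within sampling noise.

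**Figure D1:**
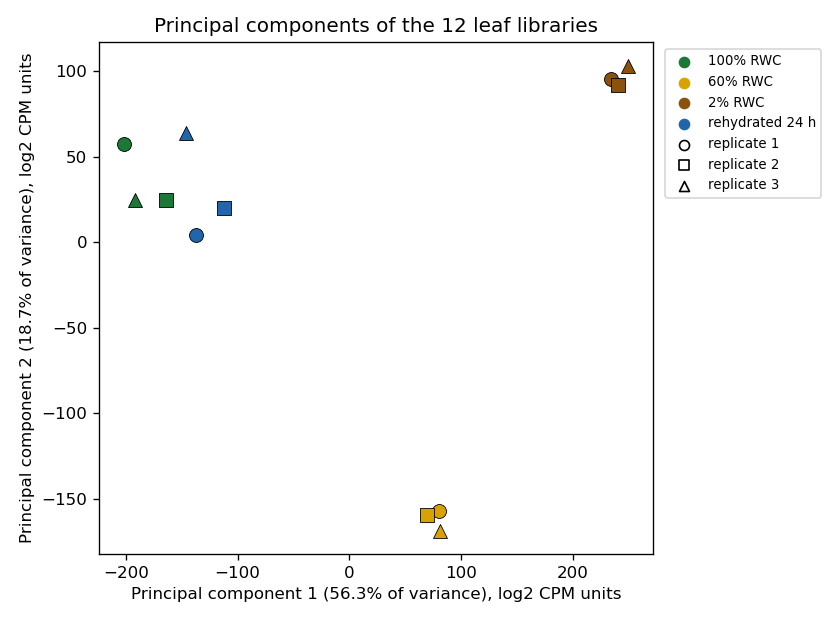
The 12 leaf libraries on the first and second principal components of log2 CPM, which held 56.3% and 18.7% of the variance, with colours for the 4 states and symbols for the 3 replicates. Fresh and rehydrated libraries lie on the left, and the 60% RWC and 2% RWC libraries form separate groups on the right.

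Partial drying to 60% RWC raised transcripts of protective proteins of desiccated tissue. Among late embryogenesis abundant (LEA) and other desiccation proteins, which are thought to shield membranes and proteins during water loss, 64 of 86 tested contigs were higher and 11 lower (66 and 13 adjusted over the list alone), adjusted p = 0.0135 with an estimated correlation. Its share of all reads went from 0.281 ± 0.074% to 4.96 ± 0.2% (SD, n = 3). Outside that list, the desiccation-related protein Cp_V2_contig_4317 rose from 629 ± 505 to 63300 ± 8170 RPKM (log2 fold 6.68, SE 0.62). Its description is spelled dessication, which the words of the list miss. Its mean log2 CPM was 13.16, against 11.08 for dehydrin 1, the list member at the highest level. The shares of reads given for the list therefore leave out an abundant desiccation transcript. Dehydrin 1 (Cp_V2_contig_15111) rose from 62.7 ± 16.3 to 8630 ± 359 (log2 fold 7.19, SE 0.31) and a LEA 6-like protein (Cp_V2_contig_45054) from 1.38 ± 0.53 to 2040 ± 17.5 (log2 fold 10.60, SE 0.29). Early light-induced proteins, thylakoid proteins linked to protection from excess light, had 25 higher and 4 lower of 30 (25 and 4 adjusted over the list alone, adjusted p = 0.0335 with an estimated correlation). This list shares 13 contigs, all described as the desiccation stress protein DSP-22 of this species, with the LEA list. DSP-22 Cp_V2_contig_36065 rose from 3.16 ± 1.83 to 992 ± 193 RPKM (log2 fold 8.35, SE 0.53), and 19.3% of its reads also matched other contigs, so its level is uncertain. An early light-induced protein 1 (Cp_V2_contig_46725) had 3 reads in the fresh libraries and a level of 153 ± 29.1 RPKM at 60% RWC (ratio 2030, 694 to 9840).

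Most called contigs of abscisic acid (ABA) synthesis and signalling and of oleosins and caleosins were higher at 60% RWC, and most called aquaporin contigs lower. Of the list of ABA synthesis and signalling, the hormone system of the drought response, 86 of 185 tested contigs were higher and 29 lower (90 and 32 adjusted over the list alone), adjusted p = 0.104 with an estimated correlation. The list had members that did not rise: the ABA receptor PYL4 contig Cp_V2_contig_12317 had no read at 60% RWC, at least 13.5-fold lower, and the member at the highest level, protein phosphatase 2C 51 (Cp_V2_contig_39930), was not called (2.67 ± 3.47 and 7.3 ± 2.7 RPKM). Without fresh replicate 1 that phosphatase was called higher, with a log2 fold of 3.63 and an adjusted p of 0.000102 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of oleosins and caleosins, coat proteins of lipid droplets, 12 of 21 tested contigs were higher and 2 lower (14 and 2 adjusted over the list alone), adjusted p = 0.0579 with an estimated correlation. A peroxygenase-like contig of the list (Cp_V2_contig_773) rose from 2.77 ± 1.6 to 495 ± 18.6 RPKM (log2 fold 7.54, SE 0.55) and an oleosin 1-like contig (Cp_V2_contig_20784) from 27 ± 11.3 to 195 ± 40.4 (log2 fold 2.91, SE 0.34). Of aquaporins, the water channels of cell membranes, 18 of 34 tested contigs were lower and 4 higher (20 and 4 adjusted over the list alone), adjusted p = 0.633 with an estimated correlation. The tonoplast aquaporin TIP1-1 (Cp_V2_contig_1841) went the other way, from 261 ± 50.3 to 7030 ± 209 RPKM (log2 fold 4.83, SE 0.43), and the aquaporin list as a whole took 0.16 ± 0.062% of reads in fresh leaves and 0.565 ± 0.028% at 60% RWC (SD, n = 3). Among antioxidant enzymes 35 of 130 tested contigs were higher and 41 lower (37 and 44 adjusted over the list alone), with a median log2 fold of -0.30 and a mean of -0.10 while camera gave the direction as up, adjusted p = 0.826 with an estimated correlation. Monodehydroascorbate reductase (Cp_V2_contig_18892), which recycles ascorbate, rose from 12 ± 3.84 to 192 ± 6.08 RPKM (log2 fold 4.14, SE 0.22). The member at the highest level, catalase isozyme 3 (Cp_V2_contig_1190), fell from 1060 ± 550 to 327 ± 28.4 RPKM (log2 fold -1.63, SE 0.36). Chaperones split, with 25 higher and 26 lower of 132 (25 and 26 adjusted over the list alone, adjusted p = 0.782 with an estimated correlation). The luminal-binding protein 5 (Cp_V2_contig_39236), a chaperone of the endoplasmic reticulum, rose from 3.28 ± 0.666 to 102 ± 10.5 RPKM (log2 fold 5.05, SE 0.44). The member at the highest level, a heat shock cognate 70 kDa protein 2-like contig (Cp_V2_contig_458), fell from 1580 ± 320 to 970 ± 49.9 RPKM (log2 fold -0.62, SE 0.21). That call lay near the threshold and was lost without fresh replicate 1 or without any 1 library of 60% or 2% RWC.

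Most called contigs of photosynthesis, cell wall, cell cycle and cell type marker lists were lower at 60% RWC. Of light-harvesting proteins 36 of 41 tested contigs were lower and 0 higher (37 and 0 adjusted over the list alone), adjusted p = 0.16 with an estimated correlation. Of photosystem and thylakoid electron transport proteins 79 of 108 tested contigs were lower and 4 higher (80 and 4 adjusted over the list alone), adjusted p = 0.0757 with an estimated correlation. Of the Calvin cycle, which fixes carbon dioxide, 44 of 79 tested contigs were lower and 1 higher (45 and 2 adjusted over the list alone), adjusted p = 0.246 with an estimated correlation. Of chlorophyll synthesis 33 of 73 tested contigs were lower and 4 higher (33 and 4 adjusted over the list alone), adjusted p = 0.182 with an estimated correlation. The Rubisco small chain Cp_V2_contig_63 went from 15700 ± 3550 to 1090 ± 112 RPKM (log2 fold -3.76, SE 0.24). The chlorophyll a-b binding protein 21 Cp_V2_contig_5361 from 832 ± 668 to 3.34 ± 1.17 (log2 fold -7.81, SE 0.84) and the photosystem II 22 kDa protein Cp_V2_contig_886, needed for the thermal release of excess light energy, from 445 ± 268 to 13.7 ± 0.908 (log2 fold -4.98, SE 0.54). Among expansins and xyloglucan endotransglucosylases (XTH), which loosen and rebuild walls, 44 of 62 tested contigs were lower and 2 higher (45 and 2 adjusted over the list alone), adjusted p = 0.0579 with an estimated correlation. An XTH 7 contig (Cp_V2_contig_4129) had no read in the 60% RWC libraries and was at least 241-fold lower than in fresh leaves, and another (Cp_V2_contig_3413) went from 520 ± 353 to 38.8 ± 5.35 RPKM (log2 fold -3.68, SE 0.60). Of cellulose synthases 60 of 94 tested contigs were lower and 1 higher (69 and 1 adjusted over the list alone), adjusted p = 0.0157 with an estimated correlation. Of pectin modification 85 of 140 tested contigs were lower and 10 higher (87 and 10 adjusted over the list alone), adjusted p = 0.246 with an estimated correlation. Of the cell cycle 83 of 224 tested contigs were lower and 15 higher (86 and 16 adjusted over the list alone), adjusted p = 0.0264 with an estimated correlation. Guard cell and stomatal lineage markers had 0 higher and 10 lower of 15 (0 and 10 adjusted over the list alone, adjusted p = 0.0579 with an estimated correlation). Epidermis and cuticle markers had 5 higher and 67 lower of 130 (5 and 70 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation). Vascular markers had 10 higher and 39 lower of 98 (10 and 40 adjusted over the list alone, adjusted p = 0.471 with an estimated correlation).

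The other contigs with the largest folds at 60% RWC, by the rule fixed in advance, came from many families. Higher were a retrovirus-related Pol polyprotein (Cp_V2_contig_47856, at least 196-fold), 2 sodium/hydrogen exchanger 4 contigs (Cp_V2_contig_47446, at least 163-fold, and Cp_V2_contig_47684, at least 80.1-fold), a contig whose annotation is divided (Cp_V2_contig_47878, at least 137-fold) and a late blight resistance protein homolog R1A-3 (Cp_V2_contig_47935, 1 read in fresh leaves, ratio 3380, 606 to 133000). The contig of divided annotation is described as an RNA helicase ddx56, and its best hit is named RACK1C. Lower were a bHLH18-like transcription factor (Cp_V2_contig_21655, at least 163-fold), a BURP domain-containing protein 16-like contig (Cp_V2_contig_20436, at least 71.6-fold), a galactinol-sucrose galactosyltransferase 1 (Cp_V2_contig_10315, at least 59.7-fold) and a ferric reduction oxidase 7 (Cp_V2_contig_6421, 2 reads at 60% RWC, ratio 1710, 473 to 14100). The bHLH18-like contig stood at 31.5 ± 38.6 RPKM in fresh leaves, an SD above the mean, so its bound rests on uneven fresh libraries. A bound of this kind sets a state of no reads at 3 counts per library, and a ratio is given with its 95% counting interval. Over the whole transcriptome, 7241 contigs were higher and 10848 lower at 60% than at 100% RWC, 38.9% of the 46494 tested, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p below 0.05. At least 2-fold higher were 4681 of these and at least 2-fold lower 9564. Every contig named above as higher or lower at 60% RWC passed that test, with adjusted p of at most 0.0348. Of the 50 lists, camera with a preset correlation called 26, and 4 of these held with an estimated correlation, namely LEA and desiccation proteins, early light-induced proteins, cellulose synthases and the cell cycle. A fit of the 6 fresh and 60% RWC libraries alone called 4450 contigs higher.

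In leaves dried to 2% RWC, desiccation proteins and early light-induced proteins stayed far above their levels in fresh leaves. Of LEA and desiccation proteins 65 of 86 tested contigs were higher and 12 lower (66 and 12 adjusted over the list alone), adjusted p = 0.0355 with an estimated correlation. Their share of reads was 3.61 ± 0.52% against 0.281 ± 0.074% in fresh leaves (SD, n = 3). The desiccation-related protein Cp_V2_contig_4317, which is not in that list, stood at 40300 ± 2030 RPKM (log2 fold 6.14, SE 0.60). Dehydrin 1 (Cp_V2_contig_15111) at 4820 ± 343 (log2 fold 6.46, SE 0.30) and Dehydrin DHN3 (Cp_V2_contig_22485) at 5740 ± 508 against 102 ± 56.2 (log2 fold 5.98, SE 0.44). Of early light-induced proteins 25 of 30 tested contigs were higher and 4 lower (25 and 4 adjusted over the list alone), adjusted p = 0.0665 with an estimated correlation. They took 1.73 ± 0.51% of reads against 0.0109 ± 0.007% (SD, n = 3). DSP-22 Cp_V2_contig_36065 reached 5170 ± 1530 RPKM (log2 fold 10.84, SE 0.58), and a second DSP-22 contig (Cp_V2_contig_43829) had 3 reads in fresh leaves and 933 ± 293 RPKM at 2% RWC (ratio 6160, 2110 to 29900). Protein phosphatase 2C 51 (Cp_V2_contig_39930), of a family that holds back ABA signalling, rose from 2.67 ± 3.47 to 621 ± 31.3 RPKM (log2 fold 7.97, SE 0.97), and the oleosin 1-like contig Cp_V2_contig_20784 reached 1210 ± 71.7 (log2 fold 5.67, SE 0.39). A heavy metal-associated isoprenylated plant protein 26-like contig (Cp_V2_contig_47824) had 1 read in fresh leaves and 191 ± 9.6 RPKM (ratio 8910, 1600 to 352000), and a wall-associated receptor kinase 2-like contig (Cp_V2_contig_47837) was at least 238-fold higher.

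RNA processing, translation factor, proteasome and autophagy lists had more higher than lower members at 2% RWC, while protease and ribosomal protein lists had more lower ones. Of RNA helicases and splicing factors 224 of 352 tested contigs were higher and 23 lower (227 and 23 adjusted over the list alone), adjusted p = 0.18 with an estimated correlation. Of translation initiation and elongation factors 126 of 231 tested contigs were higher and 20 lower (126 and 20 adjusted over the list alone), adjusted p = 0.199 with an estimated correlation. Of the proteasome, which degrades proteins, 52 of 115 tested contigs were higher and 15 lower (52 and 15 adjusted over the list alone), adjusted p = 0.459 with an estimated correlation. Of autophagy 26 of 57 tested contigs were higher and 10 lower (26 and 10 adjusted over the list alone), adjusted p = 0.384 with an estimated correlation. Senescence proteins and proteases had 36 higher and 92 lower of 185 (37 and 93 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation). Their share of reads went the other way, from 0.595 ± 0.12% in fresh leaves to 1.13 ± 0.038% at 2% RWC (SD, n = 3). Of cytosolic ribosomal proteins 199 of 443 tested contigs were lower and 39 higher (195 and 37 adjusted over the list alone), adjusted p = 0.844 with an estimated correlation. Organelle ribosomal proteins had 27 higher and 44 lower of 116 (27 and 44 adjusted over the list alone, adjusted p = 0.844 with an estimated correlation). Of the chaperones, the heat shock cognate 70 kDa protein 2-like contig Cp_V2_contig_458 was not called (1580 ± 320 and 1740 ± 52.2 RPKM, log2 fold 0.34, SE 0.21). The luminal-binding protein 5 Cp_V2_contig_39236 reached 218 ± 48.1 RPKM (log2 fold 6.26, SE 0.47), and a stromal 70 kDa heat shock-related protein (Cp_V2_contig_181), a chloroplast chaperone, rose from 294 ± 70.9 to 677 ± 41.4 (log2 fold 1.44, SE 0.17). That contig falls in the list of small heat shock proteins by its description, and of this list 6 of 29 tested contigs were higher and 6 lower (6 and 4 adjusted over the list alone), with a median log2 fold of -0.20 and a mean of -0.01 while camera gave up, adjusted p = 0.675 with an estimated correlation. A 15.4 kDa class V heat shock protein (Cp_V2_contig_23600) of the list fell from 7.07 ± 10.1 to 0.228 ± 0.259 RPKM (log2 fold -4.51, SE 1.18). In the ABA list 65 of 185 tested contigs were higher and 57 lower (66 and 57 adjusted over the list alone), with a median log2 fold of 0.14 and a mean of -0.05, adjusted p = 0.569 with an estimated correlation. The ABA receptor PYL4-like contig Cp_V2_contig_6998 had no read at 2% RWC, at least 51.5-fold lower.

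Most called contigs of photosynthesis, cell wall and aquaporin lists were lower in desiccated than in fresh leaves. Of light-harvesting proteins 38 of 41 tested contigs were lower and 0 higher (38 and 0 adjusted over the list alone), adjusted p = 0.238 with an estimated correlation. Of photosystem and electron transport proteins 82 of 108 tested contigs were lower and 9 higher (84 and 9 adjusted over the list alone), adjusted p = 0.195 with an estimated correlation. Of the Calvin cycle 52 of 79 tested contigs were lower and 2 higher (52 and 2 adjusted over the list alone), adjusted p = 0.407 with an estimated correlation. The chloroplast glyceraldehyde-3-phosphate dehydrogenase A Cp_V2_contig_435 went from 1730 ± 534 to 86.9 ± 10.5 RPKM (log2 fold -4.13, SE 0.30) and the Rubisco small chain Cp_V2_contig_63 to 893 ± 82.1 (log2 fold -3.92, SE 0.24). The chloroplast-encoded photosystem II 44 kDa protein Cp_V2_contig_418 was higher, at 921 ± 164 against 390 ± 123 RPKM (log2 fold 1.44, SE 0.27). Of expansins and XTH 54 of 62 tested contigs were lower and 1 higher (55 and 1 adjusted over the list alone), adjusted p = 0.102 with an estimated correlation. Of cellulose synthases 67 of 94 tested contigs were lower and 5 higher (68 and 5 adjusted over the list alone), adjusted p = 0.0355 with an estimated correlation. Of aquaporins 27 of 34 tested contigs were lower and 1 higher (27 and 1 adjusted over the list alone), adjusted p = 0.403 with an estimated correlation. Expansin A10 (Cp_V2_contig_9900) stood at 198 ± 136 RPKM in fresh leaves and had no read at 2% RWC, at least 417-fold lower. No read was found there either for an XTH 7 contig (Cp_V2_contig_6709, at least 356-fold lower), the aquaporin TIP2-1-like Cp_V2_contig_20265 (at least 41.2-fold), a 2-oxoglutarate-dependent dioxygenase AOP1 (Cp_V2_contig_1295, at least 380-fold), bark storage protein A (Cp_V2_contig_1650, at least 300-fold) or a protein big grain 1-like b (Cp_V2_contig_26563, at least 172-fold). The big grain 1-like contig stood at 29.8 ± 42.7 RPKM in fresh leaves, an SD above the mean, so its bound rests on uneven fresh libraries. A glutathione reductase described as chloroplastic (Cp_V2_contig_3997), an enzyme that keeps glutathione reduced, fell from 30.2 ± 13.3 to 0.278 ± 0.0307 RPKM (log2 fold -6.47, SE 0.30). Its antioxidant list had 43 higher and 35 lower of 130 (43 and 35 adjusted over the list alone, adjusted p = 0.459 with an estimated correlation). Raffinose family and trehalose synthesis, a source of protective sugars, had 44 higher and 84 lower of 143 (44 and 86 adjusted over the list alone, adjusted p = 0.548 with an estimated correlation). A galactinol-sucrose galactosyltransferase 6 contig (Cp_V2_contig_11790) was at least 62.6-fold lower. The list took 0.777 ± 0.36% of reads in fresh leaves, 0.67 ± 0.037% at 60% and 0.674 ± 0.018% at 2% RWC (SD, n = 3). Its member at the highest level, galactinol synthase 1 (Cp_V2_contig_423), went from 1180 ± 121 RPKM in fresh leaves to 2630 ± 127 at 60% RWC (2.38-fold, SE 0.23 on the log2 scale) and 1550 ± 427 at 2% RWC (log2 fold 0.61, SE 0.23). The latter call lay near the threshold. The log2 fold was 0.65 without fresh replicate 1, 0.49 without fresh replicate 2, 0.61 without any 1 library of 60% RWC and 0.35 without 2% RWC replicate 3. The contig was called in none of these fits, with an adjusted p of 0.0522 to 0.204 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

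In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12070 contigs were higher and 16240 lower at 2% than at 100% RWC, 60.9% of those tested, and the contigs named as higher or lower had adjusted p of at most 0.039. At least 2-fold higher were 8930 and at least 2-fold lower 14356. Camera called 27 lists with the preset correlation and 2 with an estimated one, LEA and desiccation proteins and cellulose synthases. The median log2 fold of all tested contigs was -0.22, and -0.20 with DESeq2's size factors.

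**Figure D2:**
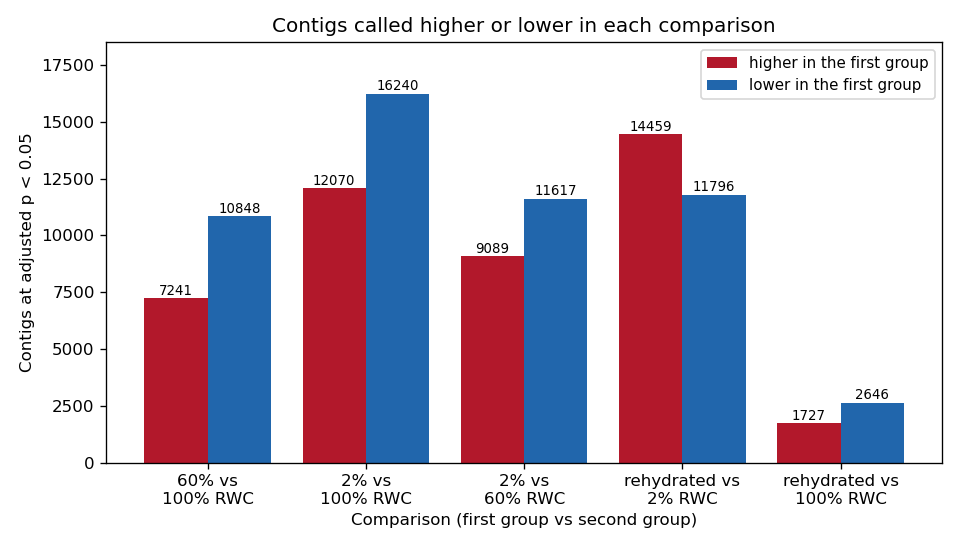
Number of contigs called higher (red) or lower (blue) in the first-named group of each of the 5 comparisons, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, out of 46494 tested. The highest bar is the 16240 contigs lower at 2% than at 100% RWC, and the lowest pair, 1727 higher and 2646 lower, is rehydrated against fresh leaves.

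Between 60% and 2% RWC, in the later part of drying, most called ribosomal protein contigs were lower and most called RNA processing contigs higher. Of cytosolic ribosomal proteins 233 of 443 tested contigs were lower and 11 higher (240 and 12 adjusted over the list alone), adjusted p = 0.841 with an estimated correlation. Their share of reads went from 1.84 ± 0.15% to 1.12 ± 0.14% (SD, n = 3). Of RNA helicases and splicing factors 156 of 352 tested contigs were higher and 19 lower (158 and 22 adjusted over the list alone), adjusted p = 0.531 with an estimated correlation. Their share of reads rose from 0.985 ± 0.03% to 1.76 ± 0.051%. Of translation factors 87 of 231 tested contigs were higher and 27 lower (94 and 28 adjusted over the list alone), adjusted p = 0.673 with an estimated correlation. LEA and desiccation proteins split, with 30 higher and 26 lower of 86 (32 and 30 adjusted over the list alone, adjusted p = 0.91 with an estimated correlation). Early light-induced proteins had 18 higher and 1 lower of 30 (18 and 2 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). DSP-22 Cp_V2_contig_36065 rose from 992 ± 193 to 5170 ± 1530 RPKM (log2 fold 2.50, SE 0.39) and the oleosin 1-like contig Cp_V2_contig_20784 from 195 ± 40.4 to 1210 ± 71.7 (log2 fold 2.75, SE 0.34). In the ABA list 85 of 185 tested contigs were lower and 26 higher (85 and 26 adjusted over the list alone), adjusted p = 0.712 with an estimated correlation. Protein phosphatase 2C 51 (Cp_V2_contig_39930) rose from 7.3 ± 2.7 to 621 ± 31.3 RPKM (log2 fold 6.52, SE 0.90).

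Most called aquaporin and lipid transfer protein contigs were lower at 2% than at 60% RWC. Of aquaporins 16 of 34 tested contigs were lower and 1 higher (17 and 1 adjusted over the list alone), adjusted p = 0.673 with an estimated correlation. TIP1-1 (Cp_V2_contig_1841) dropped back from 7030 ± 209 to 259 ± 117 RPKM (log2 fold -4.65, SE 0.42). Of lipid transfer proteins 23 of 43 tested contigs were lower and 6 higher (23 and 6 adjusted over the list alone), adjusted p = 0.441 with an estimated correlation. Epidermis and cuticle markers, which include wax synthesis, had 19 higher and 46 lower of 130 (19 and 49 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). ECERIFERUM 1 (Cp_V2_contig_17374), an enzyme of wax synthesis, stood at 10.5 ± 0.948 RPKM at 60% RWC and had no read at 2% RWC, at least 30.7-fold lower, as did a subtilisin-like protease SBT1.9 (Cp_V2_contig_16292, at least 28.1-fold) and a protein kinase EDR1 (Cp_V2_contig_23918, at least 36.1-fold), although 95.3% of the reads of the EDR1 contig also matched other contigs. In the other direction a mitotic cyclin C13-1-like contig (Cp_V2_contig_45582) with no read at 60% RWC reached 26.3 ± 5.05 RPKM, at least 205-fold higher, and an ethylene-responsive factor ERF098-like contig (Cp_V2_contig_38291) was at least 18.7-fold higher. A thaumatin-like protein 1b (Cp_V2_contig_38151) rose from 0.0912 ± 0.158 to 82.9 ± 22.6 RPKM (ratio 911, 356 to 3340). Of the metallothioneins, small metal-binding proteins, 3 of 5 tested contigs were higher and 1 lower (3 and 1 adjusted over the list alone), adjusted p = 0.441 with an estimated correlation. In all, 9089 contigs were higher and 11617 lower at 2% than at 60% RWC in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 44.5% of those tested, with adjusted p of at most 0.0174 for the contigs named. Camera called 19 lists with the preset correlation and 0 with an estimated one, where 5 had an unadjusted p below 0.05. Fry, which asks only whether the members of a list move on balance to a side, called 31.

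After 24 h under water most called desiccation protein contigs were lower and most called photosynthesis contigs higher. Of LEA and desiccation proteins 60 of 86 tested contigs were lower and 6 higher (61 and 6 adjusted over the list alone), adjusted p = 0.0758 with an estimated correlation. Their share of reads went from 3.61 ± 0.52% to 0.36 ± 0.033% (SD, n = 3). The desiccation-related protein Cp_V2_contig_4317, which is not in that list, went from 40300 ± 2030 to 1580 ± 95.8 RPKM (log2 fold -5.07, SE 0.57). Dehydrin 1 (Cp_V2_contig_15111) from 4820 ± 343 to 247 ± 39.6 (log2 fold -4.68, SE 0.28) and a Lea14 homolog (Cp_V2_contig_44233) from 114 ± 8.52 to 1.32 ± 0.355 (log2 fold -6.81, SE 0.36). Of early light-induced proteins 25 of 30 tested contigs were lower and 5 higher (25 and 5 adjusted over the list alone), adjusted p = 0.181 with an estimated correlation, with DSP-22 Cp_V2_contig_36065 at 152 ± 15.7 RPKM after rehydration (log2 fold -5.47, SE 0.45). Protein phosphatase 2C 51 (Cp_V2_contig_39930) fell to 12 ± 4.83 RPKM (log2 fold -6.08, SE 0.88) and the oleosin 1-like contig Cp_V2_contig_20784 to 76.7 ± 7.78 (log2 fold -4.37, SE 0.37). Of light-harvesting proteins 37 of 41 tested contigs were higher and 1 lower (37 and 1 adjusted over the list alone), adjusted p = 0.264 with an estimated correlation. The member at the highest level, chlorophyll a/b-binding protein Cp_V2_contig_159, was not called (1880 ± 478 and 1930 ± 618 RPKM, log2 fold -0.35, SE 0.47). Of photosystem and electron transport proteins 84 of 108 tested contigs were higher and 14 lower (84 and 14 adjusted over the list alone), adjusted p = 0.239 with an estimated correlation. Of the Calvin cycle 54 of 79 tested contigs were higher and 1 lower (55 and 1 adjusted over the list alone), adjusted p = 0.307 with an estimated correlation. Of chlorophyll synthesis 53 of 73 tested contigs were higher and 4 lower (54 and 4 adjusted over the list alone), adjusted p = 0.233 with an estimated correlation. The Rubisco small chain Cp_V2_contig_63 rose from 893 ± 82.1 to 8270 ± 1440 RPKM (log2 fold 2.83, SE 0.23) and glyceraldehyde-3-phosphate dehydrogenase A Cp_V2_contig_435 from 86.9 ± 10.5 to 1600 ± 322 (log2 fold 3.81, SE 0.29), while the chloroplast-encoded photosystem II 44 kDa protein Cp_V2_contig_418 fell to 269 ± 25.3 (log2 fold -2.18, SE 0.28).

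Most called cell wall, ribosomal protein and cell type marker contigs were also higher on rehydration, and most called RNA processing contigs lower. Of expansins and XTH 47 of 62 tested contigs were higher and 2 lower (48 and 2 adjusted over the list alone), adjusted p = 0.137 with an estimated correlation. Of cellulose synthases 65 of 94 tested contigs were higher and 3 lower (65 and 3 adjusted over the list alone), adjusted p = 0.0674 with an estimated correlation. Of aquaporins 19 of 34 tested contigs were higher and 4 lower (19 and 5 adjusted over the list alone), adjusted p = 0.589 with an estimated correlation. Expansin A10 (Cp_V2_contig_9900) went from no read to 82.6 ± 16.1 RPKM, at least 161-fold higher, and the XTH 7 contig Cp_V2_contig_3413 from 0.203 ± 0.217 to 228 ± 77.1 (log2 fold 9.61, SE 0.86). An XTH of another description (Cp_V2_contig_47839) fell, from 146 ± 11.3 to 1.52 ± 0.962 RPKM (log2 fold -6.97, SE 0.61). Of cytosolic ribosomal proteins 214 of 443 tested contigs were higher and 32 lower (212 and 32 adjusted over the list alone), adjusted p = 0.83 with an estimated correlation. Of organelle ribosomal proteins 60 of 116 tested contigs were higher and 12 lower (61 and 12 adjusted over the list alone), adjusted p = 0.62 with an estimated correlation. Of RNA helicases and splicing factors 191 of 352 tested contigs were lower and 30 higher (192 and 31 adjusted over the list alone), adjusted p = 0.239 with an estimated correlation. Guard cell and stomatal lineage markers had 11 higher and 0 lower of 15 (11 and 0 adjusted over the list alone, adjusted p = 0.0758 with an estimated correlation). Epidermis and cuticle markers had 83 higher and 16 lower of 130 (85 and 17 adjusted over the list alone, adjusted p = 0.0758 with an estimated correlation). Vascular markers had 36 higher and 16 lower of 98 (36 and 16 adjusted over the list alone, adjusted p = 0.819 with an estimated correlation). The glutathione reductase Cp_V2_contig_3997 rose from 0.278 ± 0.0307 to 56.9 ± 2.27 RPKM (log2 fold 7.25, SE 0.30), and the monodehydroascorbate reductase Cp_V2_contig_18892 fell to 20.6 ± 4.9 (log2 fold -3.74, SE 0.22).

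Transport, receptor and wall proteins were among the contigs that rose most from the dry state. With no read at 2% RWC, a multicopper oxidase LPR1-like contig (Cp_V2_contig_18364) was at least 316-fold higher, a nitrate and peptide transporter family 4.5-like contig (Cp_V2_contig_13746) at least 306-fold, a lysine-rich arabinogalactan protein 18-like contig (Cp_V2_contig_10404) at least 304-fold, the ABA receptor PYL4-like Cp_V2_contig_6998 at least 221-fold and a DRT100-like protein (Cp_V2_contig_12870) at least 214-fold. The galactinol-sucrose galactosyltransferase 6 Cp_V2_contig_6133 was at least 62.5-fold higher and the LEA protein At1g64065-like Cp_V2_contig_19809, against the direction of its list, at least 63.3-fold. The largest falls by the same rule included the LURP-one-related 10-like protein Cp_V2_contig_30029, from 565 ± 22.8 to 4.68 ± 3.55 RPKM (log2 fold -7.29, SE 0.82), the isoprenylated protein 26-like Cp_V2_contig_47824 (log2 fold -6.88, SE 0.29) and an F-box/kelch-repeat protein (Cp_V2_contig_45608, log2 fold -6.78, SE 0.60). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 14459 contigs were higher and 11796 lower after rehydration than at 2% RWC, 56.5% of those tested, with adjusted p of at most 0.000149 for the contigs named as rising or falling. Camera called 27 lists with the preset correlation and 0 with an estimated one, where 9 had an unadjusted p below 0.05. Fry called 35.

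**Figure D3:**
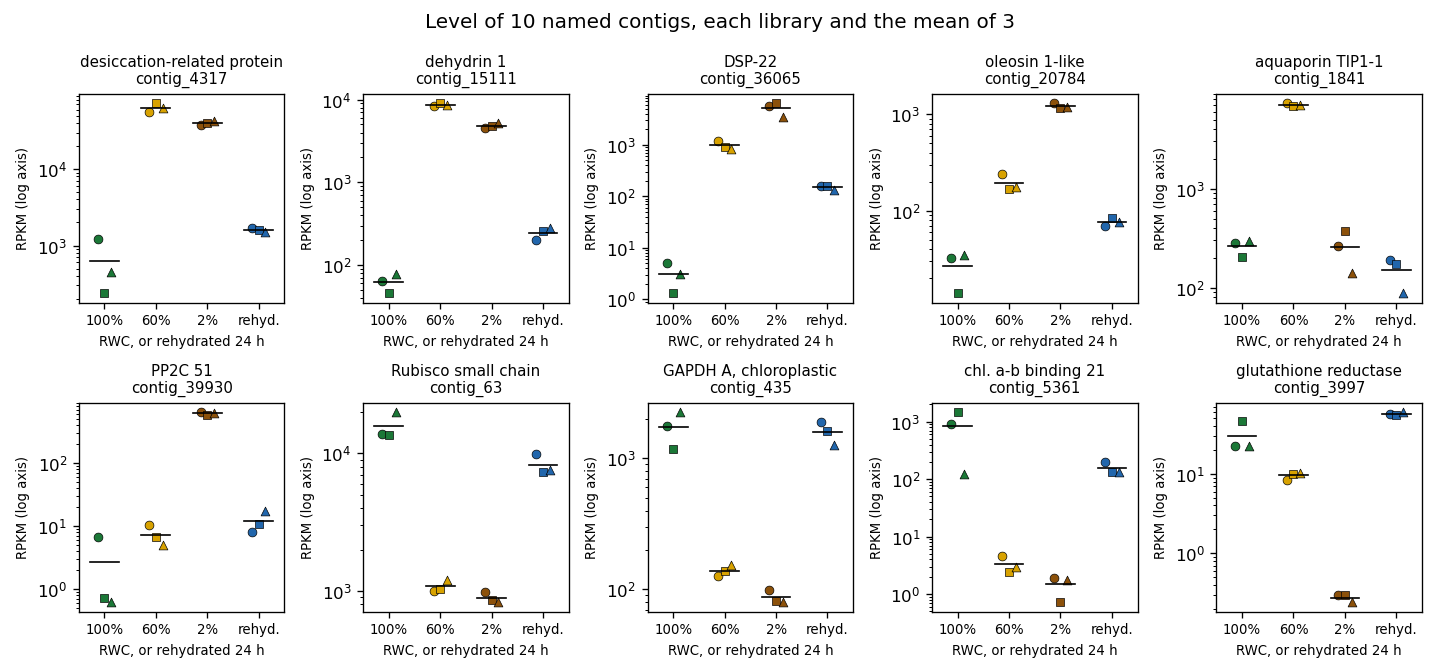
RPKM on log axes for 10 named contigs in each library (symbols for replicates 1 to 3) and the mean of each state (line), for fresh leaves (100%), 60% and 2% RWC and 24 h of rehydration. The desiccation-related protein, dehydrin 1, DSP-22, oleosin and protein phosphatase 2C 51 are low in fresh and rehydrated leaves and high at 2% RWC, the aquaporin TIP1-1 is high at 60% RWC, and the photosynthesis and glutathione reductase contigs are low at 2% RWC.

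Rehydrated leaves had not lost all the transcripts of the dry state after 24 h. Against fresh leaves, of LEA and desiccation proteins 42 of 86 tested contigs were higher and 5 lower (45 and 11 adjusted over the list alone), adjusted p = 0.0357 with an estimated correlation. Their share of reads was 0.36 ± 0.033% against 0.281 ± 0.074% in fresh leaves (SD, n = 3). Cp_V2_contig_4317, outside the list, was not called, at 1580 ± 95.8 against 629 ± 505 RPKM (log2 fold 1.07, SE 0.49). Of early light-induced proteins 26 of 30 tested contigs were higher and 0 lower (26 and 0 adjusted over the list alone), adjusted p = 0.0218 with an estimated correlation. Dehydrin 1 (Cp_V2_contig_15111) stood at 247 ± 39.6 RPKM against 62.7 ± 16.3 in fresh leaves (log2 fold 1.79, SE 0.25). The LEA 6-like protein Cp_V2_contig_45054 at 90.9 ± 14.3 against 1.38 ± 0.53 (log2 fold 5.84, SE 0.25). DSP-22 Cp_V2_contig_36065 at 152 ± 15.7 against 3.16 ± 1.83 (log2 fold 5.37, SE 0.47) and the luminal-binding protein 5 Cp_V2_contig_39236 at 140 ± 86.6 against 3.28 ± 0.666 (log2 fold 5.24, SE 0.45). The retrovirus-related Pol polyprotein Cp_V2_contig_47856 was at least 26.7-fold higher, and a Ty1-copia retrotransposon protein (Cp_V2_contig_30477) stood at 201 ± 29.6 against 0.553 ± 0.451 RPKM (log2 fold 8.28, SE 0.42). Of transketolases, enzymes of sugar interconversion, 9 of 26 tested contigs were higher and 1 lower (9 and 1 adjusted over the list alone), adjusted p = 0.598 with an estimated correlation. Of the proteasome 22 of 115 tested contigs were higher and 0 lower (31 and 0 adjusted over the list alone), adjusted p = 0.377 with an estimated correlation. Chlorophyll synthesis had 11 higher and 0 lower of 73 (13 and 0 adjusted over the list alone, adjusted p = 0.598 with an estimated correlation). It took 1.02 ± 0.15% of reads against 0.686 ± 0.12% (SD, n = 3).

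Photosynthesis lists were mixed between rehydrated and fresh leaves. Of light-harvesting proteins 8 of 41 tested contigs were lower and 0 higher (10 and 1 adjusted over the list alone), adjusted p = 0.956 with an estimated correlation. That list ranged from 0.898 to 3.03% of reads among the fresh libraries. Its member at the highest level, Cp_V2_contig_159, was lower, at 1930 ± 618 against 8140 ± 5660 RPKM (log2 fold -2.22, SE 0.49). Photosystem and electron transport proteins had 5 higher and 1 lower of 108 (0 and 0 adjusted over the list alone, adjusted p = 0.956 with an estimated correlation), with a median log2 fold of -0.02 and a mean of 0.00 while camera gave the direction as up. The Calvin cycle had 11 higher and 5 lower of 79 (13 and 6 adjusted over the list alone, adjusted p = 0.956 with an estimated correlation), with a median log2 fold of -0.17 and a mean of 0.00 while camera gave up. The Rubisco small chain Cp_V2_contig_63 of that list was lower, at 8270 ± 1440 against 15700 ± 3550 RPKM (log2 fold -1.10, SE 0.22). Of aquaporins 8 of 34 tested contigs were lower and 0 higher (11 and 0 adjusted over the list alone), adjusted p = 0.598 with an estimated correlation. Of phenylpropanoid and flavonoid synthesis, a source of phenolic compounds, 30 of 192 tested contigs were lower and 5 higher (51 and 7 adjusted over the list alone), adjusted p = 0.914 with an estimated correlation. That list took 1.06, 0.352 and 0.407% of reads in fresh replicates 1, 2 and 3. The XTH 7 contig Cp_V2_contig_4129 fell from 84.1 ± 71.7 to 0.772 ± 0.3 RPKM (log2 fold -6.95, SE 1.05). A tyrosine aminotransferase-like contig (Cp_V2_contig_2049, 41.3 ± 65.5 and 0.106 ± 0.184 RPKM) and a salicylate carboxymethyltransferase-like contig (Cp_V2_contig_4332, 43.8 ± 69.1 and 0.24 ± 0.0897) had the other largest falls, but their calls were lost without any of the rehydrated libraries, and that of the latter also without fresh replicate 1. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was then 0.0569 to 0.0679 and 0.0588 to 0.0979. Without a rehydrated library their log2 folds were -12.54 to -8.31 and -7.87 to -7.45, and without fresh replicate 1 that of Cp_V2_contig_4332 was -3.99, against -8.88 and -7.71 with all libraries.

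Fewer contigs were called between rehydrated and fresh leaves than in any other comparison, and their number hung on the libraries in the fit. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1727 contigs were higher and 2646 lower after rehydration than in fresh leaves, 9.4% of those tested, and 2-fold or more 1328 and 2161. An unadjusted p below 0.05 in the same test was reached by 11936 contigs. The fresh libraries varied widely (common biological coefficient of variation 0.539), so a contig not called here can still differ. The contigs named as higher or lower than in fresh leaves with all 12 libraries had adjusted p of at most 0.0307. A fit of the 6 fresh and rehydrated libraries alone called 201 and 179 contigs and kept 379 of 4278 calls, and limma's voom with a weight per group called 563 and 1027. Without fresh replicate 2 the counts were 5106 and 6113, without rehydrated replicate 1 they were 988 and 1215, without rehydrated replicate 2 they were 754 and 768, and without rehydrated replicate 3 the lower count was 1494. Camera called 16 lists, of which LEA and desiccation proteins and early light-induced proteins held with an estimated correlation.

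**Figure D4:**
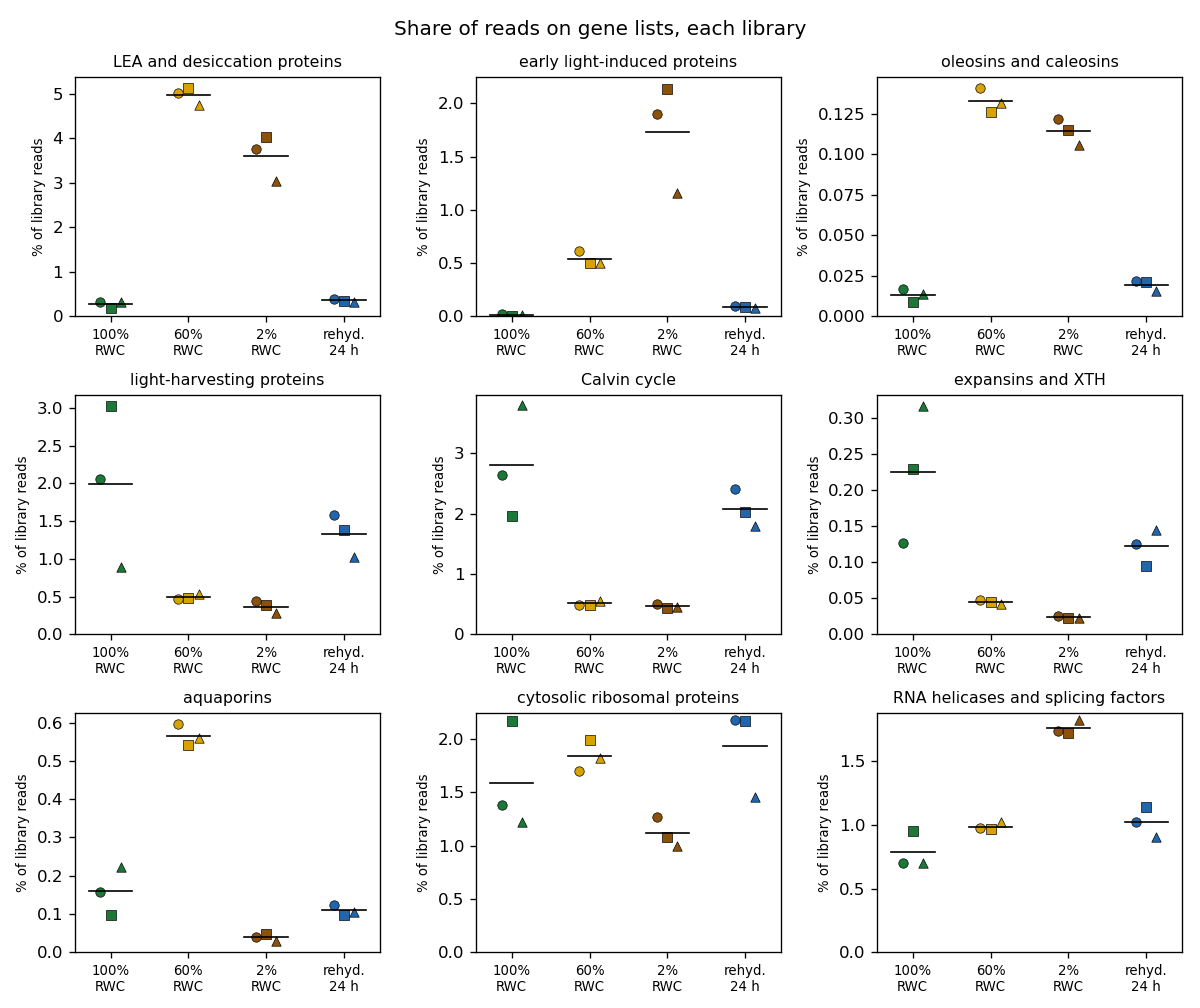
Share of each library's reads on the contigs of 9 gene lists, in percent, with symbols for replicates 1 to 3 and a line at the mean of each state. LEA and desiccation proteins went from 0.281% in fresh leaves to 4.96% at 60% RWC, 3.61% at 2% RWC and 0.36% after rehydration, and aquaporins peaked at 60% RWC with 0.565%. The LEA list does not hold the abundant desiccation-related protein Cp_V2_contig_4317.

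Most of the transcripts altered by desiccation moved back on rehydration, among them dehydrin 1 (Cp_V2_contig_15111), expansin A10 (Cp_V2_contig_9900) and the Rubisco small chain (Cp_V2_contig_63). Of 12070 contigs higher at 2% than at 100% RWC, 9714 were lower after rehydration than at 2% RWC, and of 16240 lower ones 12505 were higher, 22219 in all. Of the 28310, the test against fresh leaves still called 2923 in the direction of drying, 1020 of them higher and 1903 lower, and 563 in the opposite direction. Dehydrin 1 was among those still higher, and the chlorophyll a-b binding protein 21 Cp_V2_contig_5361 among those still lower (154 ± 36.2 against 832 ± 668 RPKM). Without fresh replicate 2 the number still different was 7484, without rehydrated replicate 1 it was 1578 and without rehydrated replicate 2 it was 1092. Independent lists of the same sizes would share 3062 and 5050 contigs in the first count and 448 and 924 in the second. In 20 simulations without any effect the comparisons, which share libraries, had on average 0 and 41.8 calls in common. With at most 87.7 calls per comparison on average, these simulations give no chance value for lists of the observed size.

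The responses at 60% and 2% RWC shared higher dehydrin 1 and lower Rubisco small chain levels. In the same direction against fresh leaves, 13317 contigs were called at both water contents, 4851 higher and 8466 lower, and 776 were called in opposite directions. The cyclin C13-1-like contig Cp_V2_contig_45582 was of the latter kind, at 0.364 ± 0.125 RPKM in fresh leaves, without a read at 60% RWC and at 26.3 ± 5.05 RPKM at 2% RWC. Independent lists would share 1880 and 3789 contigs, and simulations without effect shared 40.5 on average and 66 at most. They called only 56.6 and 55.2 contigs on average in the 2 comparisons, so their overlap is no chance value for lists of the observed size. The covariance of the log2 folds across contigs was 2.89 against 0.23 in those simulations, 4.39 against 0.0513 for desiccation and its reversal on rehydration, and 1.04 against 0.229 for desiccation and rehydration against fresh leaves. Their correlation was 0.716 against 0.824, 0.905 against 0.279 and 0.45 against 0.792 in the same order. It lay below the simulated value in both pairs that share the fresh libraries as control. The 3 fresh libraries are too few to be split, so part of the excess may come from the shared controls. Over the 4 states together, edgeR's quasi-likelihood F test called 33310 contigs at a Benjamini-Hochberg adjusted p below 0.05. A test across the states in the authors' deposited table put 27085 contigs past an FDR of 0.05. Of these 26795 were tested here, and 25385 were past both thresholds.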

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

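The tests with unique reads, counts divided by 2, voom with a weight per group and a fit without the fresh libraries were chosen after the data were seen, and the others before. Responses that kept their counts within 1.5 times under each alternative run were desiccated against fresh leaves, rehydrated against desiccated leaves, the contigs that differ across the 4 states and the return after rehydration. With each library left out in turn, 2% against 100% RWC gave 10651 to 12929 higher and 14450 to 16428 lower contigs, rehydrated against 2% RWC 12469 to 15682 and 10206 to 13514, the F test 29979 to 36654 and the return 19151 to 22972. The other responses ranged from 5363 to 9776 higher and 7942 to 12109 lower at 60% against 100% RWC, 7060 to 11199 and 9362 to 13071 at 2% against 60% RWC, and 10202 to 16087 for the overlap of the 60% and 2% responses.

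Partial drying against fresh leaves gave 4450 higher contigs with the 6 libraries alone, which estimate the spread from those states only. It gave 4356 higher and 6587 lower at an adjusted p below 0.01, and 4681 higher at a fold of at least 2, settings that are stricter by construction. At the same p, 2% against 60% RWC gave 5862 higher and 7703 lower, and the overlap of both drying responses 7971. The fit without fresh libraries gave 12733 higher and 13934 lower at 2% against 60% RWC, and 16388 and 14411 for rehydrated against 2% RWC.

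Rehydrated against fresh leaves depended most on the processing by these counts. Against 1727 higher and 2646 lower contigs, the 6 libraries alone gave 201 and 179, DESeq2's Wald test 2890 and 4581, voom with a weight per group 563 and 1027, and an adjusted p below 0.01 gave 560 and 690. Leaving out a library gave 754 to 5106 higher and 768 to 6113 lower, with the lowest counts without rehydrated replicate 2 and the highest without fresh replicate 2. Contigs still different from fresh leaves numbered 927 at an adjusted p below 0.01, and 1092 to 7484 with a library left out. The voom fit shared 1510 of the 4373 calls, and the DESeq2 test 4329. The main fit used a single spread per contig for all states, while the common biological coefficient of variation was 0.539 in fresh leaves and 0.14 to 0.264 elsewhere. Its SE and adjusted p against fresh leaves can therefore be too small. At 60% against 100% RWC voom with a weight per group gave 5452 higher and 8435 lower, but at 2% against 60% RWC 12991 and 15342, more than the main fit. The cause was not tested.

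Of 250 list results, camera with an estimated correlation kept 143 on their side of the threshold and took 107 below it, fry kept 199 and moved 44 above and 7 below, and sums per best hit kept 225. With DESeq2's size factors 249 list results and 137 named contig results were kept. The named contigs kept their side of the threshold in 1600 results with a library left out, with 40 no longer called and 4 newly called, and in 129 with DESeq2's test, with 2 no longer called. No list or named contig result called under both settings changed direction. Among all contigs, unique reads gave 1 call in the opposite direction in each comparison except rehydrated against fresh leaves, which had 0. With the replicate number as a block, which costs degrees of freedom and does not pair the samples, the counts were 7131 and 9789, 12098 and 15498, 8753 and 11334, 14244 and 11611, and 1438 and 1968 in the order of the comparisons. A change of pseudocount and settings for normalized values were not run, since the tests used counts. Depth limits the contigs with few reads: a contig without a read in a library can hold up to 0.141 to 0.203 CPM, and 1551 contigs were too low to be tested. In simulated counts for 2% against 100% RWC, 4.5% of 2-fold changes were called. Only 200 contigs were changed there, which makes the adjusted p stricter than in the real comparison with its 28310 calls. That share therefore need not hold for the real comparison, where a contig not called can still have changed.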

Other observations

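The tests of dried tissue in fresh replicate 1, of depth, of scaling between libraries and of genomic DNA were chosen after the result was seen, and the others before. Some lists outside the comparisons described so far had most of their called members on a single side. Lipoxygenases and jasmonate synthesis, a wound hormone pathway, had 0 higher and 43 lower of 55 (0 and 45 adjusted over the list alone, adjusted p = 0.447 with an estimated correlation) at 2% against 100% RWC. Fresh replicate 1 stood apart for this list, with 0.627% of reads against 0.227 and 0.133% in fresh replicates 2 and 3. WRKY transcription factors, regulators of defence genes, had 4 higher and 71 lower of 126 (5 and 80 adjusted over the list alone, adjusted p = 0.498 with an estimated correlation) at 60% against 100% RWC. That list took 0.379, 0.21 and 0.151% of reads in fresh replicates 1, 2 and 3, and 0.0596 to 0.0758% at 60% RWC. HD-Zip transcription factors had 7 higher and 66 lower of 93 (7 and 69 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation) at 2% against 100% RWC, and 5 higher and 55 lower of 93 (6 and 59 adjusted over the list alone, adjusted p = 0.441 with an estimated correlation) against 60% RWC. Heat stress transcription factors had 25 higher and 6 lower of 57 (25 and 6 adjusted over the list alone, adjusted p = 0.459 with an estimated correlation) at 2% against 100% RWC.

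Cell type and origin lists were followed at 2% against 100% RWC. Guard cell and stomatal lineage markers had 0 higher and 12 lower of 15 (0 and 13 adjusted over the list alone, adjusted p = 0.0628 with an estimated correlation), and vascular markers 14 higher and 54 lower of 98 (14 and 56 adjusted over the list alone, adjusted p = 0.447 with an estimated correlation). Epidermis and cuticle markers, which include wax synthesis, had 14 higher and 81 lower of 130 (16 and 84 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation), and root and flower markers 26 higher and 42 lower of 95 (26 and 42 adjusted over the list alone, adjusted p = 0.569 with an estimated correlation). Organelle-encoded transcripts had 29 higher and 23 lower of 122 (27 and 23 adjusted over the list alone, adjusted p = 0.844 with an estimated correlation). Ribosomal RNA and retroelements had 114 higher and 230 lower of 624 (110 and 223 adjusted over the list alone, adjusted p = 0.844 with an estimated correlation), and microbial and animal hits, which share 311 contigs with them, 70 higher and 117 lower of 310 (70 and 117 adjusted over the list alone, adjusted p = 0.929 with an estimated correlation). The latter had a median log2 fold of -0.56 and a mean of -0.13, while camera gave the direction as up.

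The fresh libraries differed from each other more than those of any other state. Low depth is argued against, since among the 11624 contigs at the highest levels their median SD was 0.439 against 0.126 at 60% RWC, 3.49 times as high. Leaves as dry as those at 60% or 2% RWC in the pool of fresh replicate 1 would bring in transcripts at higher levels in dry leaves, but 193 of 255 contigs at least 8-fold higher in it than in both other fresh libraries (75.7%) lay above the mean of every other state. Less dried leaves were not measured and stay open, as do differences between the pooled plants. Another time of day for fresh replicate 2 stays open: 8 of 15 evening clock contigs (53.3%) were highest in it, against 33.1% of all contigs and between the bounds set in advance. Of 31 morning clock contigs 1 was highest and 16 were lowest in it. Against the mean of fresh replicates 1 and 3, its median log2 difference was 0.7 for the evening and -1.86 for the morning contigs.

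Between 60% and 2% RWC, 233 of 443 ribosomal protein contigs were called lower and 156 of 352 RNA helicase and splicing contigs higher, and neither list held with an estimated correlation (adjusted p = 0.841 and 0.531). Contig length and level are argued against, since random lists matched on them to the ribosomal protein contigs had a median log2 fold of -0.02 (-0.17 to 0.11) against -0.76 observed. Scaling between libraries is argued against as well, because the gap between the medians of both lists was 1.37 (-0.20 to 0.21 in matched lists). A response of the leaves to late drying was not tested apart from these, and stays open.

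The share of reads on contigs named as ribosomal RNA or retroelements was higher in dry leaves, going in members not named as rRNA from 0.441% in fresh leaves to 0.747% at 60% and 1.175% at 2% RWC, with 0.857% after rehydration. Genomic DNA in the libraries of dry leaves is argued against, since 66.9% of the called contigs of the list were lower at 2% than at 100% RWC. Of the summed rises, 10 contigs held 89.8%, such as the Ty1-copia contig Cp_V2_contig_4554 with 11.9 ± 1.78, 1490 ± 380, 2690 ± 723 and 1870 ± 148 CPM in the 4 states (SD, n = 3) and the TNT 1-94 Pol contig Cp_V2_contig_38509 with 5.78 ± 0.854, 269 ± 79.9, 1670 ± 245 and 808 ± 447. A biological explanation was not tested, and stays open.

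The libraries were also split in other ways. In each comparison the 6 libraries allow 10 splits, too few for a share under 0.05. The real split called 18089, 28310, 20706, 26255 and 4373 contigs in the 5 comparisons, and the highest of the other splits called 0 in each, so 1 of 10 splits reached the real count. Camera's called lists numbered 26 against 25 in the highest other split (1 of 10 splits as large), 27 against 27 (2 of 10), 19 against 14 (1 of 10), 27 against 28 (2 of 10) and 16 against 25 (8 of 10). Lists are for that reason described by their called members and by the test with an estimated correlation. For the 4 states, 1 of 50 splits of the 12 libraries, the real one, reached 33310 contigs, with 2035 in the highest other. No random grouping drawn here thus gave as many calls. Every other split mixes the states within its groups and widens their spread. The splits therefore do not tell how many of the calls are due to chance.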
